A study of Mus musculus with 68 samples.

How the data were processed

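RNA was sequenced from the prefrontal cortex of 68 C57BL/6J mice at postnatal day 25, 1 library per animal label, from stranded libraries of polyadenylated RNA per the labels' protocols. The mice carried either 1 mutant copy of Adnp (labelled HT) or none (WT) and had received vehicle, fluoxetine or lithium from day 3 to day 24, about 3 weeks, through the milk of a treated mother. The labels give genotype, treatment, sex and replicate number, which make 12 groups.

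The authors deposited 1 table for all libraries, with a signal value per gene and library that is a read count divided by 1 size factor per library. The table holds 18088 genes. Salmon 0.11.2, R 3.6.0, DESeq2 1.19.11 and the mouse build GRCm38 are named per the submitters' processing notes, which do not state the role of each. The annotation release, the filter on low genes and the use of strand in counting are not given in the sources used here. Every column was a whole multiple of 1 step, so whole reads could be recovered: 100% of values came out whole within 0.01 in the library with the lowest share. In 60 of the 68 columns the step could be read from low values alone. In the other 8 the step lay within 1.2 percent of 1, and only the higher values showed it. The recovered reads numbered 22.4M to 37.5M per library (median 30.7M, M for mega), and the most abundant gene took 1.90 to 3.33% of a library.

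Tests were run on log2(value + 1) with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean and robust shrinkage. All 12 groups entered 1 fit and shared 1 estimate of the spread. Effects in both sexes are the mean of the female and male contrasts. Genes with a mean of at least 5 were tested, which kept 17922 and left out 166 (1 gene was 0 in every library). P-values were adjusted by the Benjamini-Hochberg method, and a gene passed at an adjusted p under 0.05. A fold change is on the log2(value + 1) scale, which understates the change of low genes. The test planned for raw counts was edgeR's quasi-likelihood test. Because the deposited values are normalized, limma took its place, and edgeR 4.0.16 was run on the recovered reads as an added alternative. For the genotype comparison under vehicle edgeR called 2648 genes and limma 2680, of which 2508 were shared with the same direction. Unless a tool is named, an adjusted p in the text comes from limma.

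Gene symbols came from GENCODE vM21 positions on GRCm38 (18077 genes matched), and coordinates are 1-based. The genes named were chosen by a rule: Adnp, the 12 higher and the 12 lower genes with the smallest p in each comparison that joins both sexes, 5 and 5 in each comparison of 1 sex or of a difference of effects, and the 3 smallest p where fewer than 3 genes passed. Up to 4 members with the smallest p stand for a gene list. The same rule was applied to the fits within library sets described next. Predicted genes and pseudogenes were counted and not named. Genes outside the rule are named as chosen after their values were seen. Clustered protocadherins share exons and reads at their 3' ends, and families such as ribosomal proteins have many near-identical pseudogenes, so levels of their single members are uncertain. Overlapping and antisense genes are uncertain too, because the use of strand in counting is not given.

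Libraries were divided into 3 sets on pseudogene levels, which the labels do not name. Average linkage on 1 minus Pearson's r over 361 pseudogenes gave the sets, and this step was added after the data had been seen. The number of sets was fixed at 3 and was not itself tested. Set 1 (28 libraries) held all fluoxetine libraries and 8 HT vehicle libraries. Set 2 (28) held all lithium libraries and 11 vehicle libraries of both genotypes. Set 3 (12) held 10 WT vehicle and 2 HT vehicle libraries. A fit of group by set gave each contrast within 1 set that holds both sides. For genotype in vehicle males sets 2 and 3 both hold HT and WT libraries. Set 2, the only one with both sexes of both genotypes under vehicle, was used there, and the set 3 contrast was fitted as well. For fluoxetine in WT no set holds both sides.

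A total of 36 gene lists fixed before the data were examined, for pathways and for cell types of cortex and neighbouring tissue, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The lists were not chosen on these samples. Fry's p tests movement in 1 direction and its mixed p movement in either. At the estimated correlation 1 list, cholesterol synthesis in the fluoxetine comparison of HT, passed in both fits, and no other list passed in any of the 7 comparisons tested with lists, which join both sexes. Lists were not tested by sex or for differences of effects. In 1 simulation with 200 genes changed at random, 0 of 36 lists passed with camera at the preset correlation. Its genes were drawn independently, so it cannot show how camera behaves when the genes of a list are correlated.

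The test code was checked on simulated counts for 17922 genes with 200 changed genes. The simulated counts held no library sets and no correlation between genes, so the false calls below do not cover differences between sets. In the genotype comparison under vehicle, 50.7% of genes changed 1.2-fold, 82.1% of those changed 1.5-fold and 93.9% of those changed 2-fold were recovered, with 12 false calls. Within sets the same comparison recovered 32.8%, 65.7% and 81.8%, with 6 false calls. For lithium in WT within set 2 the shares were 28.4%, 73.1% and 83.3%, with 10 false calls. For fluoxetine in HT within set 1 they were 50.7%, 68.7% and 90.9%, with 7 false calls, and for lithium in HT within set 2 they were 41.8%, 74.6% and 92.4%, with 2 false calls.

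The labels give separate replicate numbers but do not say that each library came from another litter, so p-values measure only the spread between these libraries, and pups of 1 treated mother may share effects. No library was a duplicate of another in its group: over 174 pairs within groups, the smallest chi-square per gene was 3.74 (median 20.0). Pairs across groups were not tested this way. The highest correlation between any libraries was 0.992. Xist and Ddx3y matched the sex label in all libraries: the 35 female libraries had 9682 to 27307 for Xist and 0 to 11.0 for Ddx3y, and the 33 male libraries had 0 to 144 and 998 to 1842. The alternatives tried were quantile normalization, no trend, no filter, pseudocounts of 0.5 and 5, replicate number as a block, 2 residual components, only the groups compared, and each library left out. Added later were edgeR, the library set as a term, the fit within sets, marker scores of 8 cell type and region lists as covariates, a permutation of the Adnp labels within sex, drug and set, and 3 libraries with unusual marker scores left out.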

Results

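Prefrontal cortex RNA was profiled in 68 mice of both sexes, with or without a mutant copy of Adnp, a gene for a chromatin-binding protein mutated in a syndromic form of autism. Fluoxetine is a serotonin reuptake inhibitor, and lithium is a mood stabilizer that inhibits glycogen synthase kinase and inositol monophosphatases. Under vehicle there were 8 female and 8 male HT libraries and 8 female and 7 male WT libraries. Under fluoxetine each of the 4 groups had 5 libraries. Under lithium there were 4 female and 5 male HT libraries and 5 female and 3 male WT libraries. Libraries held 22.4M to 37.5M recovered reads (M for mega). The comparisons asked what the Adnp genotype changed, what each drug changed in each genotype, and whether a drug moved HT expression towards WT.

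Adnp itself (chromosome 2, 168180986 to 168207112, GRCm38, minus strand) was not lower in the libraries labelled HT. Across all libraries it was 1.23-fold higher in HT (log2 difference 0.30, SE 0.05, adjusted p = 1.7e-05). A two-sided permutation test of the genotype labels within sex with 100000 resamples gave p = 1e-05, the smallest those resamples can give. Those labels were not held within drug or library set. With labels permuted only within sex, drug and set (55 libraries in 7 strata), the difference was 0.28 (permutation p = 1e-05 over 100000 resamples), with HT higher in 7 of 7 strata. In females under vehicle, HT libraries had 2158 ± 275 normalized counts (SD, n = 8) and WT libraries 1682 ± 435 (n = 8). In males they had 2364 ± 272 (n = 8) and 1996 ± 151 (n = 7). Under fluoxetine the HT means were 1856 ± 206 in females and 1941 ± 296 in males, against 1553 ± 222 and 1485 ± 194 in WT (n = 5 each). Under lithium HT females had 2373 ± 67.8 (n = 4) and HT males 2253 ± 198 (n = 5), and WT females had 1994 ± 153 (n = 5) and WT males 1908 ± 241 (n = 3). By limma the difference was 0.32 (SE 0.07, adjusted p = 2.1e-03) under vehicle and 0.32 (adjusted p = 0.039) under fluoxetine. Under lithium it was 0.25 (adjusted p = 0.19). Within library set 2 the vehicle difference was 0.19 (adjusted p = 0.88). With marker scores as covariates the pooled vehicle difference was 0.30 and did not pass (adjusted p = 0.092). Gene-level counts do not show which allele the reads came from, so the level of Adnp does not check the genotype labels, and every direction below is between libraries labelled HT and WT.

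Part of the difference between groups followed 3 sets of libraries that the labels do not name. WT vehicle females of set 3 (n = 5) and set 2 (n = 3), alike in every label but replicate number, differed at 3642 genes (1733 higher in set 3 and 1909 lower). WT vehicle males of sets 3 and 2 differed at 5315 genes. HT vehicle females of sets 1 and 2 differed at 5 genes and HT vehicle males at 24. HT vehicle males of sets 3 and 2 differed at 2626. The sets were cut from these same data, which favours differences between them. In WT vehicle libraries the split also followed replicate numbers, 1 to 5 in set 3 and 6 or above in set 2, which did not enter the clustering. Most WT vehicle libraries lay in set 3, and all drug-treated libraries lay in sets 1 and 2, so pooled comparisons with WT vehicle mix treatment or genotype with set. Values within 1 set are therefore given beside the pooled values.

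Under vehicle, libraries labelled HT had more RNA for Col6a2, a collagen VI chain. It stood at 1284 ± 78.8 normalized counts in HT females and 1228 ± 181 in HT males (n = 8 each), against 743 ± 79.9 in WT females (n = 8) and 663 ± 86.0 in WT males (n = 7). The fold was 1.79 (log2 0.84, SE 0.06, adjusted p = 2.7e-18). Several genes normally low in brain were higher by larger folds: Best1, a chloride channel of retinal pigment epithelium, 3.08-fold (log2 1.62, SE 0.12), Stpg1 3.11-fold, the netrin gene Ntn5 3.01-fold, the cell cycle regulator E2f2 2.27-fold, the mucin Muc2 2.57-fold and Sycp2, a protein of the meiotic synaptonemal complex, 2.45-fold. The lysosomal mannosidase Man2b2 was 1.51-fold higher (adjusted p = 3.4e-18). Vstm5 (0.49), Sec24d (0.50), Plcg2 (0.56) and Smim1 (0.53, log2) completed the 12 higher genes. Among lower genes, the clustered protocadherins Pcdhga9 and Pcdha11, cell surface adhesion proteins of neurons, stood at 0.682-fold and 0.610-fold (adjusted p = 4.5e-09 and 2.5e-08). Serpinb9 (-0.44), Tcfl5 (-1.02), Tbx1 (-1.70), Dpy19l3 (-0.24), the synaptic adhesion gene Lrrtm3 (-0.29), the kinase gene Camk2d (-0.24), Pcdhga7 (-0.37), Prelid3b (-0.20), Irak1bp1 (-0.31) and Pcdhga10 (-0.41, log2) made up the rest.

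By limma 2680 genes passed under vehicle when sets were pooled (1387 higher and 1293 lower in HT), and 96 passed within set 2 (83 higher and 13 lower; 6 HT and 5 WT libraries). Of these, 93 also passed with the same direction in the pooled fit. All 24 named genes kept their sign within set 2 and 17 of them passed, with Col6a2 at 0.82, Best1 at 1.79, Stpg1 at 1.80, Sycp2 at 1.71 and Pcdha11 at -1.03 (log2). Libraries of set 2 also entered the pooled fit, so part of this is built in. In both fits 61.0% of all tested genes and 79.7% of the 2680 pooled calls had the same sign. The amino acid transporter gene Slc6a19 (2.30, SE 0.27, adjusted p = 2.0e-08), Zfp992 (1.17) and Pcdhga11 (0.58) were among the higher genes within set 2. The lower ones held Pcdha12 (-0.57), Zbtb7c (-0.48), Wwox (-0.26), the calcium-binding protein gene Casq2 (-0.62), Klhl4, Polr3e and Prkag1 (-0.17). Tbx1 (-1.13, adjusted p = 0.33), Tcfl5 (-0.75, adjusted p = 0.22), Serpinb9 (-0.38, adjusted p = 0.054), Camk2d (-0.16, adjusted p = 0.42) and Irak1bp1 (-0.05) did not pass there. Striatal neuron markers had a median of -0.66 in HT within set 2 and 0.070 pooled (0 of 17 members passed in either, adjusted p = 0.95 and 0.97 with an estimated correlation). Olfactory bulb markers, a list added after the data were seen, had a median of 1.41 there (0 of 15 passed; camera p = 2.1e-06, and p = 0.14 with an estimated correlation).

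**Figure D1:**
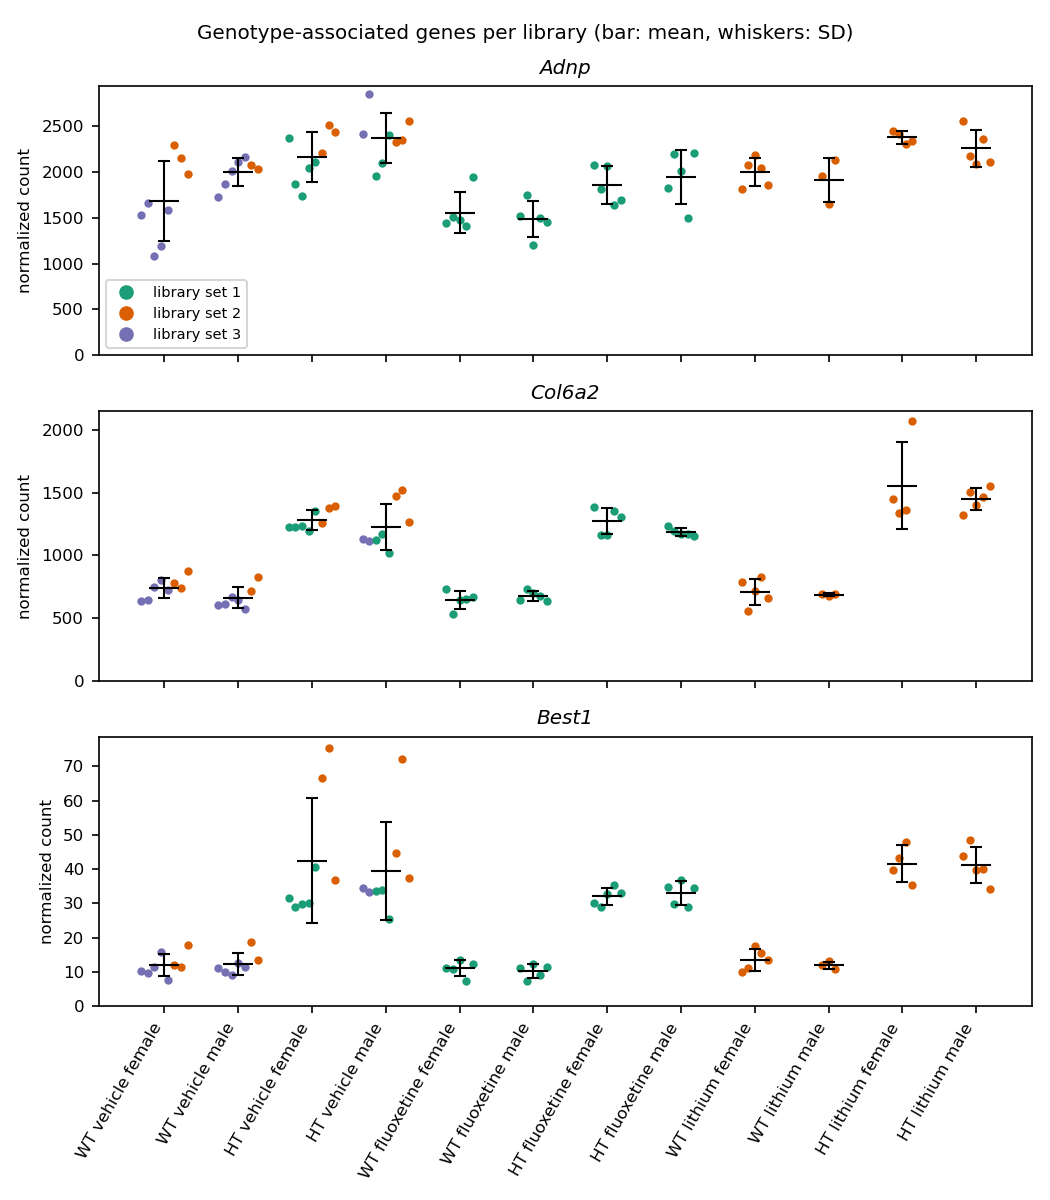
Normalized counts of Adnp, Col6a2 and Best1 in each library, by genotype and treatment, with points marked by library set. For Col6a2 the HT vehicle means were 1284 in females and 1228 in males against 743 and 663 in WT.

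The same genotype question under each drug compared libraries of 1 set, set 1 for fluoxetine and set 2 for lithium. Under fluoxetine Col6a2 was 1.86-fold higher in HT (log2 0.89, SE 0.07, adjusted p = 3.9e-15), at 1274 ± 105 in females and 1186 ± 32.3 in males against 646 ± 73.6 and 678 ± 39.3 in WT (n = 5 each). Best1 (2.92-fold), E2f2 (1.21), Man2b2 (0.49), Ntn5 (1.37), Stpg1 (1.38), Slc6a19 (3.61-fold), Pcdhga11 (0.52) and Vstm5 (0.45) were higher too. So were Xlr3a, of an X-linked lymphocyte-regulated family (4.41-fold, adjusted p = 2.6e-08), the glutathione peroxidase gene Gpx3 (0.58) and Lsp1 (1.97-fold). The 12 leading lower genes held the protocadherins Pcdhga7 (-0.55), Pcdhga9 (-0.58), Pcdhga4 (-0.44), Pcdha11 (-0.69), Pcdhgb5 (-0.51) and Pcdhgb4 (-0.58), and Slc26a6 (-0.39), Bmper (-0.27), Clpb (-0.23), Prkag1 (-0.19), Rab29 (-0.41) and Zbtb7c (-0.36, log2). Under lithium Col6a2 was 2.14-fold higher (log2 1.10, SE 0.08, adjusted p = 3.3e-17) and its partner chain Col6a1 1.74-fold higher. E2f2 (2.93-fold), Sycp2 (3.05-fold), Best1 (3.11-fold), Slc6a19 (4.30-fold), Zfp992 (1.38), Muc2 (1.44), Pcdhga11 (0.60), Sec24d (0.51), Man2b2 (0.42) and the calcium release channel gene Ryr1 (1.59-fold) rose as well. Lower in HT under lithium were the astrocyte gap junction gene Gjb6 (0.726-fold), Prkag1 (-0.30), Pcdha11 (-0.76), Pcdhga9 (-0.48), S100a1 (-0.37), Rin2 (-0.26), Polr2i (-0.39), Drap1 (-0.31), Enpp2 (-0.42), Fermt2 (-0.21), Nme1 (-0.26) and Gpc5 (-0.23, log2).

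In all, 355 genes passed under fluoxetine (238 higher and 117 lower) and 450 under lithium (266 higher and 184 lower). In the fit that estimated the spread within group and set, the counts were 510 and 805. The fluoxetine and lithium arms share no library, and in that fit 126 higher and 31 lower genes passed in both, where 6.87 and 4.47 are given by independent lists. Counting the vehicle libraries of set 2 too, 56 higher and 7 lower genes passed in all 3 arms. Leaving out WT lithium male 2 took the lithium count to 170, leaving out HT lithium female 3 to 247 and leaving out WT lithium female 5 to 257. In HT under lithium, cytosolic ribosomal protein genes and nuclear-encoded genes of oxidative phosphorylation stood lower. Of the 79 ribosomal genes 18 fell and 0 rose (0 rose and 60 fell when adjusted over the list alone; median -0.20, camera adjusted p = 4.3e-33), among them Rpl29 (-0.17) and Rpl21 (-0.24). The adjusted p = 0.17 with an estimated correlation. Of the 74 oxidative phosphorylation genes 21 fell and 0 rose (0 rose and 45 fell when adjusted over the list alone; median -0.18), among them Atp5j2 (-0.24) and Cox6b1 (-0.28), with adjusted p = 0.17 with an estimated correlation. Striatal neuron markers had a median of 0.63 in the same comparison (0 of 17 passed, adjusted p = 0.68 with an estimated correlation).

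Clustered protocadherins, whose combinations give neurons distinct surface identities, went both ways by genotype in every arm. Of 57 members, 13 rose and 12 fell in HT under vehicle (17 and 18 when adjusted over the list alone), 4 rose and 12 fell under fluoxetine (10 and 17), and 10 rose and 4 fell under lithium (17 and 11). Fry's mixed test gave adjusted p = 5.6e-63, 1.9e-34 and 8.9e-27, and 9.6e-14 for vehicle within set 2, where 3 rose and 4 fell. Pcdhga2 rose by 0.53, 0.48 and 0.63 (log2) under vehicle, fluoxetine and lithium. Pcdhga9, at chromosome 18, 37736936 to 37841870, and Pcdhga11, whose first exon lies further along the same cluster with the same last exons, moved in opposite directions.

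Col6a2, Man2b2, Best1 and Ntn5 were among the 5 leading higher genes of each sex under vehicle, and Pcdhga9 was the 1 lower gene among the leading 5 of both. In females Man2b2 (0.60), Col6a2 (0.79), Best1 (1.68), Ntn5 (1.51) and Stpg1 (1.63) led the higher genes and Tbx1 (-2.07), Pcdhga9 (-0.53), Tcfl5 (-1.05), the cyclin-like gene Ccnjl (-0.41) and Pcdhga7 (-0.40) the lower ones. In males Col6a2 (0.88), Man2b2 (0.59), Ntn5 (1.67), E2f2 (1.27) and Best1 (1.56) were higher and Serpinb9 (-0.52), Pcdha11 (-0.80), Dpy19l3 (-0.30), Pcdhga9 (-0.57) and Lrrtm3 (-0.34) lower. In females 314 genes passed when pooled (209 higher, 105 lower) and 28 within set 2. In males 755 passed (523 higher, 232 lower) and 21 within set 2 (3 HT and 2 WT libraries). Within set 3 (2 HT and 5 WT males) 185 passed (117 higher, 68 lower). No gene passed limma's test of a genotype difference between the sexes, where 662 had an unadjusted p under 0.05. EdgeR also called 0, with 637 at an unadjusted p under 0.05. Mre11a (-0.34), Nup37 (-0.71) and Tmem219 (0.42) had the smallest p (adjusted p = 0.97 each).

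Fluoxetine in HT went with lower RNA for cholesterol synthesis. Of 24 members of that list, 13 fell and 0 rose (20 fell when adjusted over the list alone; median -0.18), among them lanosterol synthase Lss (0.860-fold, log2 -0.22, SE 0.04, adjusted p = 3.3e-03), Cyp51 (-0.18) and Insig1, a sterol-sensing brake on the pathway (0.862-fold, adjusted p = 5.9e-03). Insig1 had 1680 ± 134 normalized counts in HT fluoxetine females and 1916 ± 53.1 in males (n = 5 each), against 1989 ± 189 and 2185 ± 172 under vehicle (n = 8 each). Camera gave adjusted p = 6.1e-24, and adjusted p = 4.5e-03 with an estimated correlation. Within set 1, with 10 fluoxetine and 8 vehicle libraries, Insig1 (-0.23) and Stard4 (-0.22) fell, 20 members fell when adjusted over the list alone, and the median was -0.16 (adjusted p = 0.035 with an estimated correlation). With the 8 marker scores as covariates 22 of 24 members were lower, at a median of -0.11 pooled and -0.12 within set 1 (adjusted p = 0.014 and 0.011 with an estimated correlation). Lss and Insig1 did not pass in those fits. Lss stood at -0.097 pooled and -0.087 within set 1 (adjusted p = 0.32 and 0.49). Insig1 stood at -0.18 in both (adjusted p = 0.14 and 0.063).

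Other genes lower under fluoxetine in HT included some of vessels and of the circadian clock, while no list of either passed at an estimated correlation. The zinc finger gene Klf4, present in endothelium, stood at 0.600-fold (log2 -0.74, SE 0.13, adjusted p = 1.4e-03), the intermediate filament gene Nes at 0.713-fold, the basement membrane gene Col4a1 at -0.35, Adgrl4 at -0.30, Tns2 at -0.37, the smooth muscle gene Smtn at -0.38, Adgre5 at -0.38, Fam129a at -0.42, Helz2 at -0.42 and Gper1 at -0.40. Per3 of the circadian clock stood at 0.833-fold (SE 0.04, adjusted p = 3.8e-04). Of 13 endothelial markers 3 fell and 0 rose (4 fell when adjusted over the list alone; median -0.16; Tie1 -0.33), with adjusted p = 0.12 with an estimated correlation. Of 9 mural cell markers 3 fell and 0 rose (4 fell when adjusted over the list alone; median -0.17; Abcc9 -0.32), with adjusted p = 0.13 with an estimated correlation. Marker medians of glia were -0.26 for myelinating oligodendrocytes (0 of 18 passed, 2 fell when adjusted over the list alone; adjusted p = 0.45 with an estimated correlation), -0.18 for oligodendrocyte precursors (1 of 12 fell, 6 when adjusted over the list alone; Enpp6 -0.42; adjusted p = 0.11 with an estimated correlation), -0.10 for astrocytes (2 of 16 fell, 2 when adjusted over the list alone; adjusted p = 0.18 with an estimated correlation) and -0.078 for microglia (0 of 16 passed, 1 fell when adjusted over the list alone; adjusted p = 0.50 with an estimated correlation). Vessel and glia lists were not tested against each other. Of 16 clock genes 2 fell and 0 rose (5 fell when adjusted over the list alone; Per2 -0.41), with adjusted p = 0.11 with an estimated correlation. The leading higher genes were the complex I subunit Ndufa5 (1.22-fold, adjusted p = 3.3e-03), tubulin cofactor Tbca (1.33-fold), Mrps35 (0.20), Rsl24d1 (0.21), Lsm8 (0.31), Mnat1 (0.31), Smyd3 (0.19), Commd2 (0.27), Pfn2 (0.15), Tram1l1 (0.18), Aimp1 (0.23) and Srp9 (0.18, log2).

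In total 218 genes passed for fluoxetine in HT (73 higher and 145 lower), and 30 within set 1 (6 higher and 24 lower), of which 22 were shared. Libraries of set 1 also entered the pooled fit, and 80.4% of all tested genes had the same sign in both fits. All 24 named genes of the pooled fit kept their sign within set 1 and 10 of them passed. Per3 (-0.24), Fam129a (-0.44), Nes (-0.53), Smtn (-0.43), Klf4 (-0.66), Tns2 (-0.36), Helz2 (-0.43), Gper1 (-0.42), Smyd3 (0.21) and Rsl24d1 (0.20) passed there, and Ndufa5 (0.16, adjusted p = 0.23), Tbca (0.18, adjusted p = 0.39), Lss (-0.16, adjusted p = 0.13) and Col4a1 (-0.29, adjusted p = 0.073) did not. Myh9 (-0.28), Ptgis (-0.59), Swap70 (-0.28) and Zfp738 (-0.29) also fell within set 1, and Ube2e2 (0.19), Hmox2 (0.17), Elmo1 (0.16) and Pigx (0.28) rose. With the marker scores as covariates, among them an endothelial score that holds part of the effect, 7 genes passed pooled and 12 within set 1. Klf4 then stood at -0.56 (adjusted p = 0.14), Nes at -0.31 (adjusted p = 0.23) and Per3 at -0.16 (adjusted p = 0.079), while Fam129a (-0.40, adjusted p = 0.016) passed pooled and Zfp738 (-0.32, adjusted p = 2.8e-03) within set 1. Pooled with the scores, Col4a1 stood at -0.13 (adjusted p = 0.30), Adgrl4 at -0.12 (adjusted p = 0.37) and Adgre5 at -0.21 (adjusted p = 0.15). Without HT vehicle male 5 the count within set 1 was 0, and without HT fluoxetine female 1 it was 116.

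By sex, 21 genes passed for fluoxetine in HT females (3 higher and 18 lower). Xbp1 (0.29), Dnaja4 (0.26) and the pentraxin gene Nptx2 (0.36) rose, and Per3 (-0.34), the matrix gene Tnxb (-0.65), Adgre5 (-0.50), Gkn3 (-0.91) and the taurine transporter gene Slc6a6 (-0.24) fell most clearly. Within set 1, 6 passed, among them Per3 (-0.30) and Tnxb (-0.60), both with adjusted p = 0.040. Leaving out HT vehicle female 4 gave 246 genes in females and leaving out HT vehicle female 8 gave 2. In HT males limma called 0 genes (1221 at an unadjusted p under 0.05) and edgeR called 1. Tns2 (-0.47), Klf2 (-0.80) and Creb3l2 (-0.36) had the smallest p there (adjusted p = 0.076 each). The test of a difference between the sexes called 0 genes by limma (799 at an unadjusted p under 0.05) and 0 by edgeR (814), with Xbp1 at -0.40 (adjusted p = 0.19), Tmcc1 at -0.26 (adjusted p = 0.45) and Dok3 at -0.78 (adjusted p = 0.94).

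In WT, fluoxetine and vehicle libraries never shared a set, so drug and set cannot be told apart there. Pooled, 974 genes passed (563 higher and 411 lower), and with the set as a term limma called 0 (350 at an unadjusted p under 0.05). Commd2 (1.28-fold, adjusted p = 6.6e-04), Churc1 (0.43), Hsdl1 (0.24), Polr2d (0.29), Prmt1 (0.28), Mrpl43 (0.21), Sstr3 (0.26), Odc1 (0.27), Atic (0.20), Rps13 (0.29), Ndufs5 (0.29) and Rps15a (0.32) were higher. The sterol dehydrogenase gene Nsdhl (0.861-fold, adjusted p = 2.4e-03), the endothelial regulators Klf2 (0.651-fold) and Sox17 (-0.39), Rarres2 (-0.47), Sfxn1 (-0.17), Dpm1 (-0.32), Tcim (-0.58), Pou3f1 (-0.43), Adgrl4 (-0.28), C2cd2 (-0.25), Heg1 (-0.28) and Timp3 (-0.28) were lower. Of the cholesterol synthesis list 7 fell and 1 rose (13 and 1 when adjusted over the list alone; median -0.10), with adjusted p = 0.56 with an estimated correlation. Of the 79 ribosomal genes 34 rose and 1 fell (50 and 2 when adjusted over the list alone; adjusted p = 0.56 with an estimated correlation). The test of a fluoxetine effect that differs by genotype called 0 genes by limma (2187 at an unadjusted p under 0.05) and 1 by edgeR (2179 at an unadjusted p under 0.05). The synaptic adhesion gene Nlgn3 (0.28, adjusted p = 0.099), Zfp142 (-0.24, adjusted p = 0.099) and Gper1 (-0.51, adjusted p = 0.10) were nearest to passing.

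**Figure D2:**
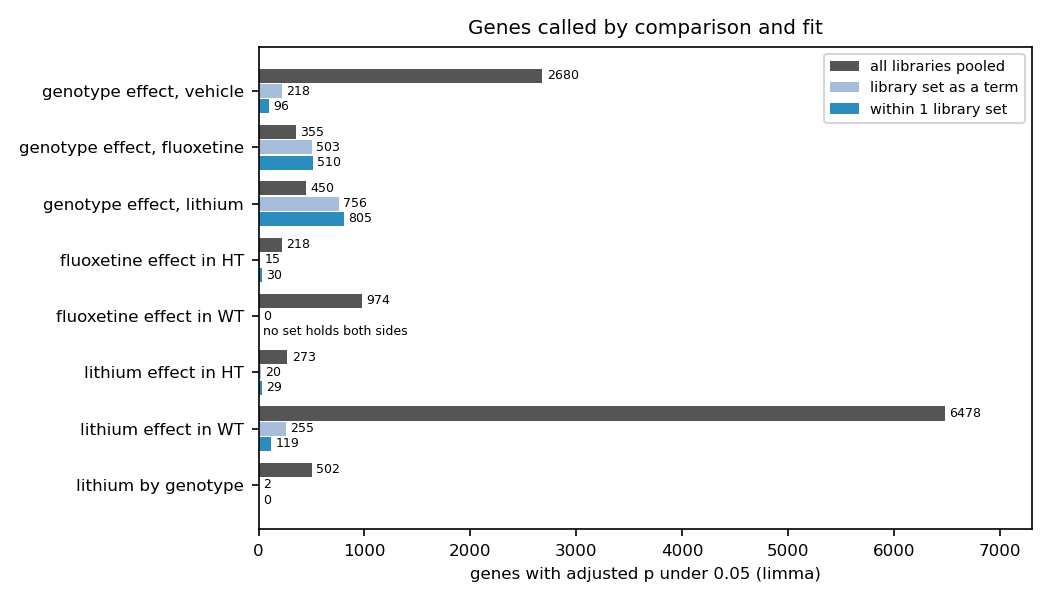
Total number of genes with an adjusted p under 0.05 for genotype in each arm, each drug in each genotype and lithium by genotype. Bars show all libraries pooled, the library set as a term and the fit within 1 library set. Lithium in WT had 6478 genes pooled and 119 within set 2.

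Lithium in HT raised Castor2, a negative regulator of amino acid signalling to mTORC1, 1.24-fold (log2 0.31, SE 0.04, adjusted p = 3.0e-06) and the endoplasmic reticulum chaperone Hspa5 1.22-fold (SE 0.06, adjusted p = 7.4e-03). It lowered Frat1, a binding protein of the lithium target glycogen synthase kinase, to 0.723-fold (log2 -0.47, SE 0.08, adjusted p = 1.7e-03), from 235 ± 24.4 to 183 ± 22.6 normalized counts in females (n = 8 and 4) and from 241 ± 36.1 to 162 ± 24.0 in males (n = 8 and 5). Txnip, a glucose-responsive regulator of thioredoxin, stood at 0.816-fold (adjusted p = 7.8e-03). Other higher genes were Ube4a (0.17), Bcl2l13 (0.16), Wipf3 (0.31), Ccdc6 (0.26), Mtmr4 (0.21), Snap29 (0.18), Cemip (0.32), Arhgef2 (0.18), Ankib1 (0.15) and Klhdc10 (0.14), and other lower genes were Gbp2 (-0.48), Dcdc2b (-0.62), Loxl1 (-0.49), Cdkn1c (-0.34), Zfp414 (-0.21), Gpx3 (-0.27), Alg5 (-0.22), Tcte2 (-0.37), Pnma1 (-0.31) and Ripply2 (-0.53, log2). Of 20 genes of the unfolded protein and integrated stress response 8 rose and 1 fell (11 and 1 when adjusted over the list alone; median 0.12), among them Pdia4 (0.30), Hyou1 (0.26) and Pdia6 (0.19). Camera gave adjusted p = 4.0e-09, and adjusted p = 0.14 with an estimated correlation. The mean centred log2 score of the list was 0.14 in lithium and -0.051 in vehicle HT males, and -0.0043 and -0.018 in females. This difference between the sexes was not tested for the list. Of 10 inositol genes 0 passed and 4 rose when adjusted over the list alone (median 0.09; the inositol transporter gene Slc5a3 0.20), with adjusted p = 0.33 with an estimated correlation.

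In total 273 genes passed for lithium in HT (185 higher and 88 lower) and 29 within set 2 (22 higher and 7 lower), of which 23 were shared. Libraries of set 2 also entered the pooled fit, and 74.2% of all tested genes had the same sign in both fits. All 24 named genes of the pooled fit kept their sign within set 2 and 11 of them passed. Within set 2, with 9 lithium and 6 vehicle libraries, Castor2 (0.22), Snap29 (0.22), Ccdc6 (0.26), Bcl2l13 (0.15), Ankib1 (0.16), Frat1 (-0.48), Txnip (-0.44, adjusted p = 2.4e-04), Gbp2 (-0.53), Dcdc2b (-0.72) and Zfp414 (-0.26) passed, and Hspa5 (0.25, adjusted p = 0.12) did not. The prostaglandin synthase gene Ptgs2 (0.49), the cyclin gene Ccnd2 (0.32), Noxred1 (1.12), Klhl42 (0.20), Slc35e2 (0.19), Col4a3bp (0.16), Slc38a9 (0.22) and Trib2 (0.26) also rose within set 2, and the kinase gene Pnck (-0.33) and Vstm2l (-0.40) fell. With the marker scores as covariates 117 genes passed pooled and 10 within set 2. Within set 2 Txnip (-0.43, adjusted p = 9.2e-06) passed with the scores. Castor2 (0.19, adjusted p = 0.10), Frat1 (-0.42, adjusted p = 0.0502), Ccdc6 (0.16, adjusted p = 0.25) and Gbp2 (-0.45, adjusted p = 0.19) did not. Striatal neuron markers had a pooled median of 0.79 under lithium in HT and 0.61 within set 2 (0 of 17 passed in either, adjusted p = 0.64 and 0.61 with an estimated correlation). Olfactory bulb markers had a median of -0.77 within set 2 (0 of 15 passed; camera p = 2.7e-03, and p = 0.35 with an estimated correlation). Without HT vehicle male 8 the count within set 2 was 2, and without HT lithium female 4 it was 59.

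By sex, 21 genes passed for lithium in HT males (13 higher and 8 lower). Castor2 (0.36), Snap29 (0.25), Hspa5 (0.42), Pdia4 (0.45) and Bcl2l13 (0.18) rose, and Frat1 (-0.57), Ctsw (-1.15), Pnma1 (-0.44), B3galt6 (-0.33) and Map3k7cl (-0.78) fell. Within set 2 limma called 0 in males (850 at an unadjusted p under 0.05). In HT females it called 0 (1447 at an unadjusted p under 0.05; edgeR 0 and 1429), with Ube4a (0.19), Anapc13 (-0.42) and Rpl23a (-0.26) nearest (adjusted p = 0.19 each). The test of a difference between the sexes called 0 genes (598 at an unadjusted p under 0.05; edgeR 0 and 574), with H2-M3 (0.83), Elp4 (-0.35) and Fam221a (-1.25) at the smallest p.

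In WT, lithium raised Atf4, the transcription factor of the integrated stress response, from 3174 ± 366 to 3645 ± 547 normalized counts in females (n = 8 and 5) and from 3103 ± 158 to 4115 ± 436 in males (n = 7 and 3). Within set 2, with 8 lithium and 5 vehicle libraries, Atf4 was the most clearly changed gene (log2 0.44, SE 0.06, adjusted p = 1.8e-06; 0.30 pooled). Cwc27 (0.39), Minos1 (0.29), the glutaredoxin gene Glrx (0.28), March11 (0.56), the immediate early gene Ier5 (0.50), Ociad2 (0.34), Jtb (0.34), Sat1 (0.39), Fam213a (0.25) and Phf23 (0.25) rose with it. Lrp1b (-0.52, adjusted p = 3.9e-05), the axon guidance receptor gene Robo1 (-0.33), beta-catenin Ctnnb1 (-0.24), the glutamate receptor gene Grin3a (-0.24), Cntn5 (-0.47), Ahi1 (-0.28), Zfr2 (-0.26), Nat8f6 (-1.89), Pnck (-0.26), Tmem91 (-0.45), Hps1 (-0.34) and Ppp1r21 (-0.18) fell. Frat1 fell in WT too, to 145 ± 11.2 in females and 149 ± 19.7 in males from 224 ± 35.4 and 237 ± 36.3 (0.645-fold pooled; -0.43 within set 2, adjusted p = 0.043). Of 26 immediate early genes 2 rose within set 2 and 0 fell (8 rose when adjusted over the list alone; median 0.41; Ptgs2 0.48, Bdnf 0.40, Dusp6 0.44), with adjusted p = 0.23 with an estimated correlation. Pooled, the median of the same list was -0.11 (2 rose and 0 fell; adjusted p = 0.97 with an estimated correlation), so its direction depended on the vehicle libraries used. Of the 20 stress response genes 2 rose (4 when adjusted over the list alone), Atf4 and Sesn2 (0.31), with adjusted p = 0.23 with an estimated correlation. Of 74 oxidative phosphorylation genes 6 rose and 0 fell (29 and 0 when adjusted over the list alone; Atp5o 0.16, Atp5e 0.32), with adjusted p = 0.23 with an estimated correlation. Striatal neuron markers had a median of -0.85 there (0 of 17 passed, adjusted p = 0.64 with an estimated correlation) but 0.21 pooled (1 rose; adjusted p = 0.93 with an estimated correlation), and olfactory bulb markers 0.47 (0 of 15 passed; p = 0.71 with an estimated correlation).

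Pooled, 6478 genes passed for lithium in WT (3340 higher and 3138 lower), against 119 within set 2 (77 higher and 42 lower), of which 105 were shared. The 12 leading higher genes of the pooled fit were Pdgfb (1.38-fold, adjusted p = 2.4e-07), Il6ra (1.55-fold), the neuropeptide precursor gene Vgf (1.52-fold), Tubb5 (0.45), Slc35f6 (0.38), Polr2m (0.23), Paqr8 (0.32), Arl6ip1 (0.33), Pdrg1 (0.45), Uap1l1 (0.54), Wipf3 (0.46) and Sdhd (0.39). The lower ones were Cxxc4 (-0.41), Zc3h6 (-0.56), Frat1, Lrp1b, Robo1, Nanos1 (-0.33), Klf7 (-0.33), Agbl5 (-0.59), Iqcc (-0.34), Arhgap20 (-0.42), Dgkb (-0.39) and Ssbp2 (-0.24). All 24 kept their sign within set 2 and 16 passed, among them Pdgfb (0.34), Il6ra (0.41) and Vgf (0.39). Libraries of set 2 also entered the pooled fit, and 67.2% of all tested genes had the same sign in both fits. Leaving out WT vehicle male 7 or 6 gave 16 or 17 genes within set 2, and leaving out WT lithium male 3 gave 302. With both genotypes joined in set 2, 322 genes passed for lithium (224 higher and 98 lower), with the smallest p among higher genes for Atf4 (1.24-fold, SE 0.04, adjusted p = 5.0e-07), Cwc27 (1.22-fold, adjusted p = 2.3e-05) and Ptgs2 (1.40-fold, adjusted p = 3.0e-05), and among lower genes for Pnck (0.816-fold, adjusted p = 1.3e-06), Ctnnb1 (0.869-fold, adjusted p = 1.0e-04) and Frat1 (0.730-fold, adjusted p = 1.4e-04). In HT alone Atf4 did not pass within set 2 (0.18, adjusted p = 0.13), and under lithium Atf4 was lower in HT than in WT (-0.26, adjusted p = 1.9e-04 within set 2). The limma test of a lithium effect that differs by genotype called 0 genes within set 2, so Atf4 did not pass it.

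**Figure D3:**
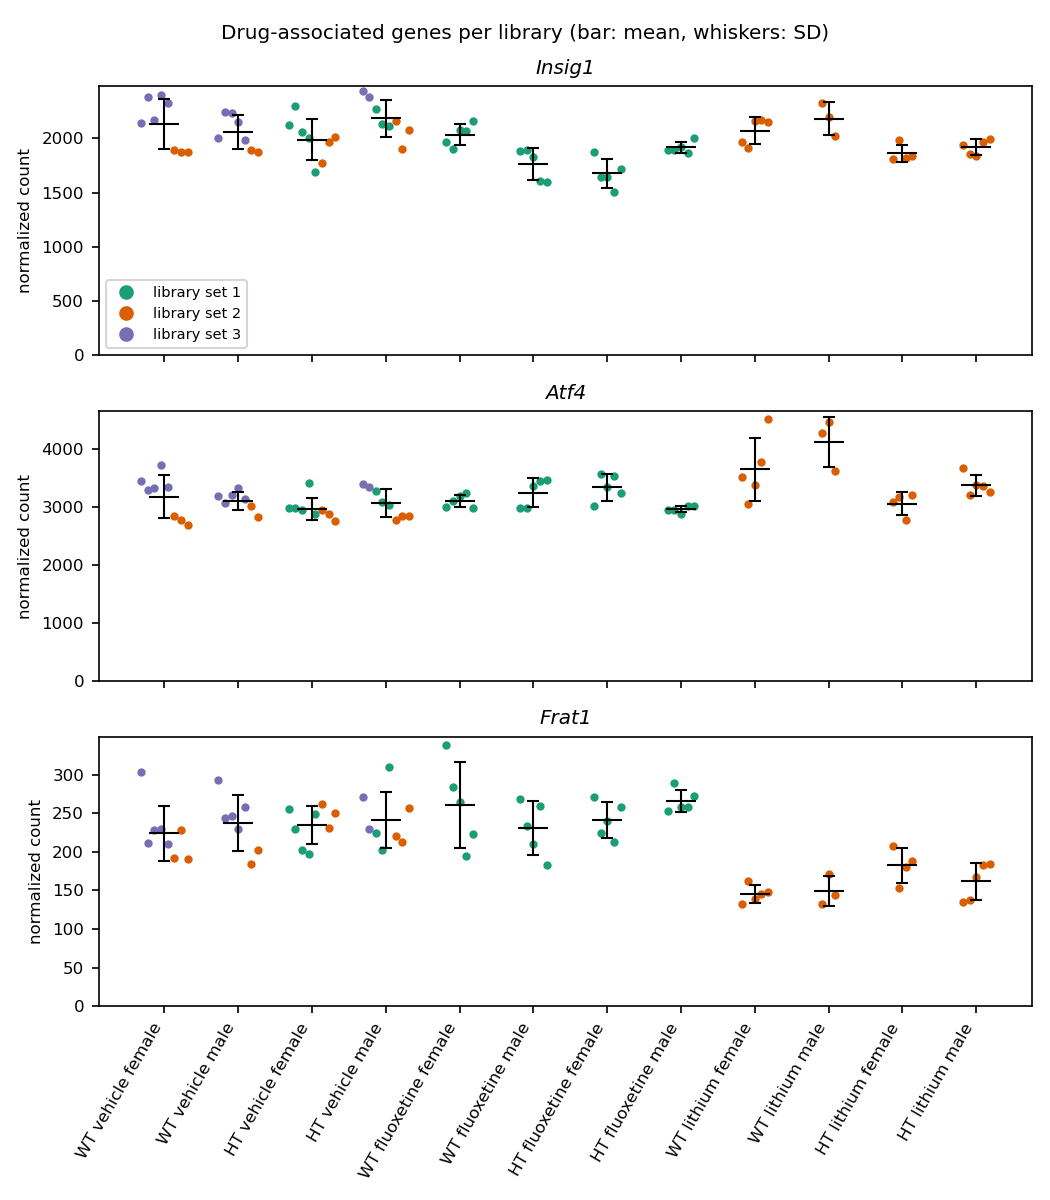
Normalized counts of Insig1, Atf4 and Frat1 in each library, by genotype and treatment, with points marked by library set. Frat1 means under lithium were 183 and 162 in HT females and males and 145 and 149 in WT, against 224 to 241 under vehicle.

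A lithium effect that differs by genotype was called at 502 genes when sets were pooled (206 with the effect higher in HT and 296 lower). The axon guidance receptors Dcc (0.41) and Robo1 (0.31), with Lrp1b (0.44), Ptprd (0.27) and Lrrc7 (0.41), had higher log2 effects in HT than in WT. Cstb (-0.55), the ribosomal genes Rps21 (-0.63), Rpl32 (-0.40) and Rps10 (-0.42), and Drap1 (-0.34) had lower ones (adjusted p from 7.8e-03 to 0.012). Within set 2 limma called 0 genes (1606 at an unadjusted p under 0.05), with Lrp1b at 0.52 (adjusted p = 0.066). With the library set as a term 2 passed, and with marker scores as covariates 0.

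**Figure D4:**
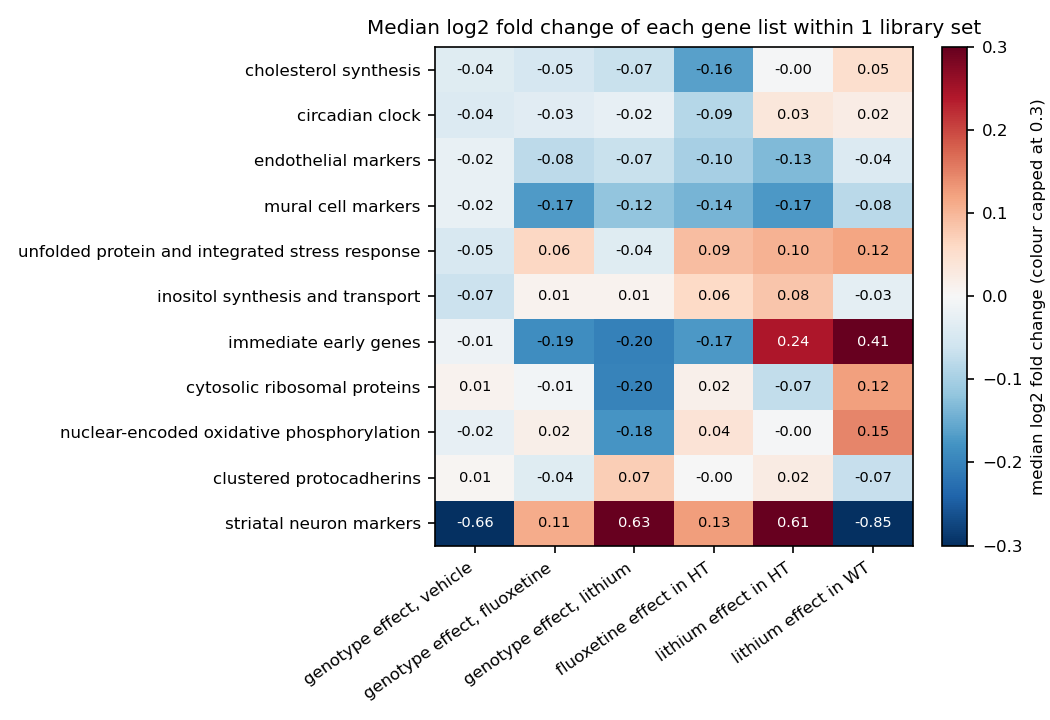
Median log2 difference of the members of 11 gene lists in 6 comparisons within library sets. Cholesterol synthesis had a median of -0.16 for fluoxetine in HT, and cytosolic ribosomal proteins had -0.20 for genotype under lithium.

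Whether a drug moved expression back towards WT was asked by correlating, across genes, the drug effect in HT with the genotype effect. Genes are not independent replicates, so p-values came from permutation of the library labels. With the HT vehicle libraries halved so that no library served both effects, over 50 splits, the mean r was 0.07 for fluoxetine (permutation p = 0.59 over 99 relabellings; covariance 0.0038) and 0.17 for lithium (permutation p = 0.23; covariance 0.0096). With the HT vehicle libraries shared, r was -0.13 (permutation p = 0.30) and 0.01 (permutation p = 0.09), where simulated effects of 0 with the same shared libraries gave -0.43 and -0.41. With the genotype effect taken from the other drug's arm and the drug effect from its own set, r was -0.05 for fluoxetine (permutation p = 0.51; 10 drug and 8 vehicle libraries) and 0.01 for lithium (permutation p = 0.61; 9 and 6). Of 805 genotype-called genes 499 (62.0%) had a fluoxetine effect opposite to the genotype effect, and of 510 genes 238 (46.7%) had an opposite lithium effect. These shares were not compared with relabelled libraries, so they do not show a move towards WT. The median fluoxetine effect was -0.026 for the genes higher in HT and 0.022 for the lower ones (log2). With the other arm's genotype effect, 2 genes passed for both fluoxetine and genotype, 1 of them in opposite directions, and 0 genes passed for both lithium and genotype. No correlation lay outside the relabelled range.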

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

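The tests of the library sets, of lithium itself, of the Adnp difference by set, by label and by permutation within strata, of position near Adnp and of cell mixture were chosen only after those results had been seen. The predictions for mislabelled libraries, germ line genes, drug against genotype and other splits of the libraries were written before those tests were run, though the germ line list itself was written after the first genotype results.

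The counts of genes called against WT vehicle were large, with 6478 for lithium. Within set 2 lithium in WT called 119 genes, with fewer vehicle libraries. Simulated counts without sets also lost recovery there, at 50.7% pooled and 28.4% within set 2 for genes changed 1.2-fold. WT vehicle females of sets 3 and 2, with no difference in drug or genotype, differed at 3642. The sets were cut from these same data, so part of that count is built in. The split also followed replicate numbers, 1 to 5 in set 3 and 6 to 8 in set 2, which did not enter the clustering. Library sets can thus add to large counts without a drug difference, by an amount not measured independently here. Marker scores of cell types and regions as covariates, with no set term, left 425 genes, against 255 with the set as a term, but within set 2 they gave 322 against 119 without them, so with the set held fixed they did not remove the calls. Lithium itself was tested by looking up the pooled WT calls in HT libraries of set 2: 53.0% had the same sign, as did as many in 744 of 1960 relabellings (share 0.380; relabelled median 49.9%), which leaves lithium open as a cause of the rest. The 119 genes called within set 2 had the same sign in HT in 82.4% (share of relabellings 0.0306), and the 29 called in HT had it in WT in 93.1% (share 0.0482), while the 273 pooled HT calls had it in WT in 75.5% (share 0.0821), above 0.05.

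Adnp RNA was higher in libraries labelled HT, and the label HT alone does not set a direction to expect. The difference was 0.30 (log2) over all libraries, and 0.32 within set 1 under fluoxetine, more than 2 SE above 0, and with labels permuted within sex, drug and set it was 0.28 (permutation p = 1e-05), so the library sets do not account for it. With genes called in another arm as a score, 0 of 68 libraries lay on the other genotype's side, which excludes mislabelled single libraries but not a swap of the labels as a whole. A difference that goes with the genotype labels is left. Whether the mutant allele gives the added reads was not tested, since reads by allele are not analysed here.

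A group of 63 genes passed by genotype in all 3 arms, 56 higher and 7 lower in libraries labelled HT. Of these, 3.17% (Sycp2 and Gm20716) lay within 20 Mb of Adnp, against 2.26% of all tested genes. For this group, that goes against a strain variant near Adnp as the main cause. The lower vehicle genes Tcfl5 and Prelid3b, outside this group, also lie on chromosome 2 within 20 Mb of Adnp. With marker scores of 8 cell types and regions as covariates 95.2% of the group (60 of 63) passed under fluoxetine, at a median size of 1.03 times the first. The calls in that arm thus do not rest on these scores. This does not decide on dissection or cell mixture. Olfactory bulb and striatal markers differed little by genotype there (medians 0.19 and 0.11), so those scores could change little. The genes had been chosen for passing in that arm, and cortical neurons, astrocytes and microglia had no score. An earlier test of mixture with residual components was dropped because such components cannot change a group difference. Germ line genes as a class gave a smallest adjusted camera p of 0.271 over the arms, but this excludes little, because genes already called were left out and the members' median level was 35.9 against 424 for all tested genes.

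In 100 splits of the libraries within sex, the real one included, fluoxetine in HT (218 genes; highest other split 1), lithium in HT (273; 0), lithium in HT males (21; 2), genotype under fluoxetine (355; 32), genotype under lithium (450; 5) and genotype in vehicle females (314; 216) were reached by 1 split, the real one. The splits did not hold the library sets fixed, so except for genotype under fluoxetine and under lithium, where all libraries share a set, the sets may add to a real count that follows them. Fluoxetine libraries in HT all lay in set 1 and lithium libraries in set 2, against HT vehicle libraries at 8, 6 and 2 in sets 1 to 3, and WT vehicle libraries lay at 0, 5 and 10. For genotype under fluoxetine and under lithium 1 in 100 is the smallest share that these splits can give. All splits treat libraries as independent, so effects shared by pups of 1 treated mother or litter are not excluded. Lithium in WT (6478; 4701) was reached by 1 as well, and its highest other split put 7 libraries of set 3 and 1 of set 2 on the lithium side, and so followed the library sets. Genotype under vehicle (2680; 4235), fluoxetine in WT (974; 3072) and the lithium effect by genotype (502; 853) were reached by 2 splits each. For genotype under vehicle the higher split had 8 libraries of set 3 on its WT side and 4 on its HT side. For genotype in vehicle males (755; 4405) and fluoxetine in HT females (21; 214) 5 splits reached the count, so chance cannot be excluded, and splits with several times the real count point to structure among the libraries. The comparisons with 0 calls were reached by all 100 splits: genotype by sex (highest other 3493), fluoxetine in HT males (1), fluoxetine by sex (54), lithium in HT females (31), lithium by sex (740) and fluoxetine by genotype (488). Within sets, genotype under vehicle (96; 43), fluoxetine in HT (30; 12) and lithium in HT (29; 1) were reached by 1 split, the real one. These counts rest on few libraries: fluoxetine in HT fell to 0 without HT vehicle male 5, and lithium in HT to 2 without HT vehicle male 8. Lithium in WT (119; 398) was reached by 3 splits, so that count alone does not set the real grouping apart from all others.

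The lithium effect by genotype differed at 502 genes in the pooled test of the difference, against 0 within set 2. The genes singled out by that test were Dcc (0.41), Lrp1b (0.44), Robo1 (0.31), Ptprd (0.27), Lrrc7 (0.41), Cstb (-0.55), Rps21 (-0.63), Rpl32 (-0.40), Rps10 (-0.42) and Drap1 (-0.34).

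Single libraries far from the rest of their group were sought for 10 measures only, 7 genes, the reads and 2 marker scores, chosen after the named genes were known. Of 110 tests, each of 1 measure in 1 group, 9 flagged such a library, where 5.5 are given by chance. WT fluoxetine female 5 had 1944 normalized counts of Adnp (others 1404 to 1502, n = 5), HT lithium female 4 had 2073 of Col6a2 (1342 to 1451, n = 4), and HT vehicle male 7 had 72.2 of Best1 (25.5 to 44.7, n = 8). HT vehicle female 4 had 3406 of Atf4 (2747 to 2975, n = 8), WT vehicle female 1 had 303 of Frat1 (191 to 230, n = 8), and HT lithium female 2 had 1982 of Insig1 (1815 to 1839, n = 4). The olfactory bulb marker score of HT fluoxetine male 1 was -1.47 (0.67 to 1.49, n = 5). The striatal marker score was 2.14 in HT vehicle male 7 (-0.88 to -0.38, n = 8) and 1.53 in WT fluoxetine female 3 (-0.85 to -0.20, n = 5).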

How the results depend on the processing

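The Adnp level was refitted with quantile normalization, edgeR, the library set as a term and each library left out, and stayed higher in HT. The count for genotype under fluoxetine moved by over 1.5 times only with 2 residual components. Counts for genotype under vehicle and for each drug were larger pooled than with the set as a term or within sets. Within sets fewer vehicle libraries entered, and no pooled subset of equal size was run. Lost power was thus not separated from the sets. Unless stated, the cause of a change was not tested. The alternatives of the first group were fixed before the data were examined. Dropping the trend or the filter and pseudocounts of 0.5 and 5 moved no count by over 1.5 times. Quantile normalization gave 139 genes for lithium in HT, 5 in HT males and 4 for fluoxetine by genotype. Only the groups compared gave 858 for genotype under vehicle, 495 for lithium in HT, 80 for fluoxetine in WT, 4254 for lithium in WT and 1 for lithium by genotype. With 2 residual components, which by construction leave group differences unchanged and shrink only the spread, counts were 5132 for genotype under vehicle, 998 under fluoxetine and 1141 under lithium, 959 for fluoxetine and 2341 for lithium in HT, 3234 for fluoxetine in WT, 897 for fluoxetine and 3023 for lithium by genotype; within sets they were 243 for genotype, 349 for fluoxetine and 284 for lithium in HT, and 318 for lithium in WT.

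With the replicate number as a block, counts were 502 for genotype in females, 398 for fluoxetine in HT (47 in females, 50 in males), 3746 for lithium in HT (274 in females, 2343 in males), 4003 for fluoxetine in WT, 8 for fluoxetine by genotype and 1150 for lithium by genotype; no other count moved by over 1.5 times. Replicate numbers followed the sets under vehicle. Numbers 6 to 8, used only there, all lay in set 2, and vehicle numbers 1 to 5 lay in sets 1 and 3. With that block the drug comparisons thus rest mostly on vehicle libraries of sets 1 and 3. Over 66 pairs of groups the mean correlation was -0.0018 for the same number and 0.0008 for others (lowest -0.467). Single numbers thus did not pair the libraries, but that check does not address numbers 1 to 5 against 6 to 8.

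Settings added after the data were seen follow. EdgeR on recovered reads gave 1 gene each for fluoxetine in HT males and fluoxetine by genotype. With the library set as a term counts were 218 for genotype under vehicle (80 in females, 176 in males), 756 under lithium, 15 for fluoxetine in HT (12 in females), 20 for lithium in HT (1 in females), 0 for fluoxetine and 255 for lithium in WT, and 2 for lithium by genotype. Within sets they were 96 (28 and 21), 805, 30 (6), 29 (0 in males), 119 for lithium in WT and 0 for lithium by genotype. With only the libraries compared in that fit, fluoxetine in HT had 3 and lithium in WT 7. With marker scores as covariates counts were 646 for genotype under vehicle and 1431 under lithium, 7 for fluoxetine and 117 for lithium in HT, 439 for fluoxetine and 425 for lithium in WT, 1 for fluoxetine and 0 for lithium by genotype; within sets 12 for fluoxetine and 10 for lithium in HT and 322 for lithium in WT. Without the 3 libraries with unusual marker scores they were 91 for fluoxetine in HT, 3 for fluoxetine and 188 for lithium by genotype, and within sets 8 for fluoxetine and 13 for lithium in HT. The correlation of fluoxetine with genotype effects turned from 0.07 to -0.13 with shared HT vehicle libraries and to -0.048 with the other arm's genotype effect.

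With each library left out in turn, Adnp ranged from 0.28 to 0.31, genotype under vehicle from 1730 to 4155 (without WT vehicle male 5 and 6; 1775 without male 2), females 207 to 558 (WT vehicle female 5 and 7; 505 without 8), males 291 to 2981 (WT vehicle male 5 and 6; 2285 without 7, and 1771 and 1735 without HT vehicle male 1 and 2), and within set 52 to 94 (52 without WT vehicle male 6). Genotype by sex stayed at 0 to 0, genotype under fluoxetine ranged from 276 to 448 and under lithium from 170 to 594. Fluoxetine in HT ranged from 111 to 432 (HT fluoxetine female 2, HT vehicle female 4), females 2 to 246, where each of the 13 libraries moved it, males 0 to 6 (HT vehicle male 6), and within set 0 to 116. Fluoxetine in WT ranged from 338 to 1969 (WT fluoxetine female 2, WT vehicle male 6), by genotype 0 to 8 (WT vehicle male 7) and by sex 0 to 2 (HT fluoxetine female 1). Lithium in HT ranged from 61 to 379 (61 without HT lithium female 3), females 0 to 1 (HT lithium female 2), males 1 to 78 (HT lithium male 1, HT vehicle male 6), and within set 2 to 59. Lithium in WT ranged from 4961 to 7340 and within set from 16 to 302, by genotype from 0 to 1492 (WT lithium male 2, WT vehicle male 6; 19 without HT lithium female 3), and by sex 0 to 0.

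Each library whose removal moved a count by over 1.5 times is given by replicate number with the count without it. For fluoxetine effect in HT (218 with all), HT fluoxetine female 1: 352, 2: 111, 3: 117, 5: 145 and HT fluoxetine male 1: 137, 3: 142 and HT vehicle female 4: 432, 7: 126, 8: 120. For fluoxetine effect in HT, females (21 with all), HT fluoxetine female 1: 139, 2: 4, 3: 7, 4: 4, 5: 5 and HT vehicle female 1: 13, 2: 4, 3: 9, 4: 246, 5: 64, 6: 6, 7: 4, 8: 2. For fluoxetine by sex in HT (0 with all), HT fluoxetine female 1: 2 and HT vehicle female 4: 1, 5: 1. For fluoxetine effect in HT, within library set (30 with all), HT fluoxetine female 1: 116, 2: 10, 3: 10, 5: 7 and HT fluoxetine male 1: 11, 2: 17, 3: 14 and HT vehicle female 1: 11, 2: 9, 3: 12, 4: 58 and HT vehicle male 3: 3, 4: 46, 5: 0. For fluoxetine effect in HT, males (0 with all), HT fluoxetine male 5: 2 and HT vehicle male 3: 1, 4: 4, 6: 6. For lithium effect in HT (273 with all), HT lithium female 1: 111, 2: 180, 3: 61 and HT lithium male 1: 108, 2: 82 and HT vehicle female 1: 124, 2: 169, 6: 171 and HT vehicle male 3: 125, 5: 120. For lithium by genotype (502 with all), HT lithium female 1: 294, 3: 19 and HT lithium male 1: 83, 2: 285 and HT vehicle female 1: 236, 6: 288, 8: 311 and HT vehicle male 1: 1015, 2: 1047, 3: 141, 6: 245, 7: 267, 8: 293 and WT lithium female 1: 223, 5: 37 and WT lithium male 2: 0 and WT vehicle female 1: 246, 4: 324, 5: 145 and WT vehicle male 1: 196, 2: 194, 5: 115, 6: 1492, 7: 1044. For lithium effect in HT, within library set (29 with all), HT lithium female 1: 13, 2: 11, 3: 7, 4: 59 and HT lithium male 1: 3, 2: 7, 4: 47 and HT vehicle female 6: 9, 7: 12, 8: 3 and HT vehicle male 6: 11, 7: 13, 8: 2. For lithium effect in HT, females (0 with all), HT lithium female 2: 1. For genotype effect, lithium (450 with all), HT lithium female 3: 247 and WT lithium female 5: 257 and WT lithium male 2: 170. For lithium effect in HT, males (21 with all), HT lithium male 1: 1, 2: 1, 3: 3, 4: 13, 5: 50 and HT vehicle male 1: 4, 2: 9, 3: 4, 4: 6, 5: 8, 6: 78, 7: 55. For fluoxetine by genotype (0 with all), HT vehicle female 8: 3 and HT vehicle male 2: 2 and WT fluoxetine female 3: 3 and WT fluoxetine male 3: 1 and WT vehicle female 6: 2, 7: 3, 8: 2 and WT vehicle male 6: 2, 7: 8. For genotype effect, vehicle, males (755 with all), HT vehicle male 1: 1771, 2: 1735, 3: 410, 4: 473, 6: 371, 7: 393, 8: 474 and WT vehicle male 1: 357, 2: 306, 3: 442, 5: 291, 6: 2981, 7: 2285. For fluoxetine effect in WT (974 with all), WT fluoxetine female 2: 338, 5: 577 and WT fluoxetine male 4: 430 and WT vehicle female 4: 514, 5: 481 and WT vehicle male 1: 606, 2: 508, 5: 612, 6: 1969, 7: 1596. For lithium effect in WT, within library set (119 with all), WT lithium female 5: 57 and WT lithium male 2: 43, 3: 302 and WT vehicle female 6: 59, 7: 53, 8: 67 and WT vehicle male 6: 17, 7: 16. For genotype effect, vehicle, females (314 with all), WT vehicle female 5: 207, 7: 558, 8: 505. For genotype effect, vehicle (2680 with all), WT vehicle male 2: 1775, 5: 1730, 6: 4155. For genotype effect, vehicle, within library set (96 with all), WT vehicle male 6: 52.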

Other observations

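The genes, the germ line list and the marker scores in this part were chosen only after results had been seen, while the predictions for the germ line class and for drug against genotype were written before those tests were run.

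Single genes higher in libraries labelled HT in every arm included several that are normally transcribed outside the brain, with log2 differences under vehicle within set 2, fluoxetine and lithium of 1.52, 1.28 and 1.29 for the meiotic cohesin gene Rec8, 1.40, 1.03 and 1.40 for Rnf17, 1.51, 1.61 and 1.51 for Prss50, and 1.99, 2.14 and 1.85 for Xlr3a. Other germ line genes, tested as a class, did not pass limma's camera test (adjusted p = 0.271 in each arm). Of its 30 members 1, 2 and 3 were higher. The calcium release channel gene Ryr1 was higher by 0.43, 0.40 and 0.67, Myh7 by 0.46, 0.38 and 0.36, skeletal actin Acta1 by 0.39, 0.29 and 0.26, and cardiac troponin Tnnt2 by 0.55, 0.54 and 0.32, while muscle genes were not tested as a group. Col6a1, whose product assembles with that of Col6a2, was higher by 0.43, 0.61 and 0.80. The antigen presentation gene Cd74 (0.47, 0.51 and 0.36), the integrin gene Itga4 (0.39, 0.44 and 0.58) and the protocadherin gene Pcdhb17 (0.26, 0.27 and 0.35) rose too. These genes were chosen from the shared genes after their values were seen.

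Each drug was asked whether it moves genes back towards WT, with the genotype effect taken from the other set. The lowest correlation was -0.048, for fluoxetine, with p = 0.51 over relabelled libraries, so a small effect in either direction is not excluded.

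Marker scores varied between libraries of 1 dissection label, from -1.06 to 2.20 for striatal neurons (SD 0.989) and from -2.28 to 3.16 for the olfactory bulb (SD 1.68). The first residual component held 18.1% of the variance within groups, with Eomes, Tbx21, Doc2g, Scgn and Cdhr1 of the olfactory bulb among its leading genes, and the second held 6.89%.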
